A study of Mus musculus with 24 samples.

How the data were processed

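The 24 libraries were made from polyadenylated RNA of mouse corpus callosum, extracted with the Qiagen RNeasy Micro kit and prepared with the TruSeq stranded mRNA kit, per the labels' protocols. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. The deposited table holds 1 FPKM value for each of 54446 versioned Ensembl mouse gene IDs and each library, as its name says. FPKM divides the fragments of a gene by its length and by the library's total, so a gene's value also falls when other genes take more of the library. Total FPKM ran from 462521 to 496350, so the values are not TPM. Of the IDs, 53229 were found with their version in GENCODE M21 (GRCm38), whose coordinates are printed, and 54409 were matched to a symbol. All sample columns of the table were used, and no library was left out of the main tests.

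Depth was read from the low values, which the method takes to be whole multiples of what 1 fragment is worth for a gene. Of 124652 values of up to 20 fragments in 6167 low genes, 66.6% lay within 0.1 of a whole multiple (79.0% in genes with 1 annotated transcript), against 20.0% by chance. The lowest library, cuprizone BTKi 5, had 85.9% of the deepest library's fragments and the second lowest 96.7%. On simulated values of 40771 genes the largest error of a library's relative depth was 3.44%. That method assumes depths within 1.4 times of each other. The simulated depths lay within that range, so the error given does not cover a wider one. FPKM is not a count, so no count test was run. Fragment counting limits low genes most, and changes near the pseudocount are understated.

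Samples were grouped by the labels into naive vehicle, naive BTKi, cuprizone vehicle and cuprizone BTKi. The 68 replicate pairs differed by a log2 spread of 0.0837 to 0.184, and no pair was close enough to be 1 library deposited again. Genes detected, the percent of FPKM in mitochondrial genes, in the 10 top genes and in haemoglobin genes gave no adjusted p under 0.05 for cuprizone under vehicle or for BTKi in cuprizone or in naive mice (exact permutation tests, smallest adjusted p = 0.277). Cuprizone under BTKi was tested after the data were seen. There more genes were detected, 15193 ± 73.4 against 14994 ± 62.4 (SD, n = 8 and 4; exact permutation p = 0.00404, adjusted p = 0.0162), and the other 3 measures gave adjusted p from 0.537 to 0.750.

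Genes with a mean FPKM of at least 0.5 over the 24 libraries (15216) were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with all 4 groups in 1 model, no covariate, and Benjamini-Hochberg adjustment within each comparison at 0.05. The comparisons were cuprizone against naive under vehicle and under BTKi, BTKi against vehicle in cuprizone and in naive mice, and the difference of the last 2. The mean ± SD values are on the FPKM scale and SE values on the log2 scale. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

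These tests, the alternatives below, 34 gene lists and the rule for naming genes were chosen before the data were examined, and anything added later is named as such. The lists were mature oligodendrocyte and myelin, newly formed oligodendrocyte, oligodendrocyte precursor, integrated stress response, homeostatic microglia, disease-associated microglia, Fc receptor and BTK signalling, complement, interferon response, MHC class I, MHC class II, cytokines and chemokines, phagocytosis and lysosome, cholesterol biosynthesis, cholesterol efflux and LXR targets, reactive astrocyte, general astrocyte, proliferation, immediate early genes, general neuron, striatal neuron, hippocampal neuron, choroid plexus, ependyma, endothelium, mural cells, fibroblast and meninges, B cell, T and NK cell, monocyte and border macrophage, neutrophil, red blood cell, mitochondrially encoded and sex-linked. They came from textbook knowledge, not from these samples. The 32 lists with at least 3 measured members were tested.

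A list score is the mean over measured members of the gene-centred log2 value in each library. Scores were compared with two-sided exact permutation tests over all 495 splits of 8 against 4 libraries, 12870 of 8 against 8 or 70 of 4 against 4. For the difference of the BTKi effects 100000 permutations of the drug labels within naive and within cuprizone mice were drawn. The p-values were adjusted over the 32 lists. Counts adjusted over the list alone apply Benjamini-Hochberg to the members' limma p-values. As alternatives, camera compared each list with the other genes, with a preset correlation of 0.01 and with an estimated one. The other alternative was fry, which tests whether the genes of a list move, on balance, one way and compares them with no other genes. For scores, 95% intervals come from a linear model over the 4 groups, which takes their spread as equal. The SD of the disease-associated microglia score was 0.568 in cuprizone vehicle and 0.332 in cuprizone BTKi. It was 0.0719 in naive vehicle and 0.0411 in naive BTKi. For such scores the intervals of BTKi in cuprizone mice are too narrow and those in naive mice too wide.

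The genes named for cuprizone under vehicle and for BTKi in cuprizone and in naive mice follow 3 rules. The first takes the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 FPKM in 1 group and libraries that do not overlap, leaving out predicted genes and pseudogenes. The second takes up to 4 called members of each described list with the largest change, or, where none was called, up to 2 with the smallest p, given as values. The third names genes whatever their values: Btk, Mbp, Mog, Gfap, Aif1, Trem2, Itgax, Cd68, P2ry12, Apoe, Fcgr2b, Pdgfra, Csf1r and Spp1. A few genes that these rules also pick are not reported here. For the difference of the BTKi effects the 5 smallest p are named, and for cuprizone under BTKi only genes named elsewhere. A few genes outside these rules are marked as named after their values were seen.

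Alternatives for the gene counts were pseudocounts of 0.1 and 1, no filter or a mean of at least 2 FPKM, median ratio scaling, quantile normalization, a fit with only the libraries of the 2 groups, array weights, robust eBayes, the replicate number as a block, a 2-fold minimum, and leaving out each library in turn. Lists were also tested after median ratio scaling, with the median over members and with the block. After the data were seen, the striatal score as a covariate was added, as was leaving out libraries with a choroid plexus score under -1.5. The return of cuprizone changes under BTKi was measured as the correlation across genes over 70 splits of the cuprizone vehicle libraries, with 100 permutations of the drug labels. Up to 100 other splits of the libraries were drawn for each count.

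The tests were run on simulated data of the same 15216 genes with 50 genes changed at each of 4 folds. At folds of 1.25, 1.5, 2 and 4 the cuprizone comparison under vehicle recovered 64.0%, 94.0%, 100.0% and 100.0% of the changed genes, with 11 false calls. BTKi in cuprizone recovered 64.0%, 94.0%, 96.0% and 100.0% (8 false calls), BTKi in naive mice 38.0%, 90.0%, 100.0% and 100.0% (9), the difference of the BTKi effects 30.0%, 80.0%, 86.0% and 100.0% (8) and cuprizone under BTKi 56.0%, 98.0%, 96.0% and 100.0% (8). For BTKi in cuprizone, a list change of -0.3219 was found as -0.3166 and 0 of 50 unchanged lists had an exact permutation p under 0.05. A true slope of -0.2 in the test of return was found as -0.198 and a slope of 0 as -0.0221. The simulated noise was drawn independently for each gene and the lists were 20 random genes, so correlation between genes was left out. The real striatal list had an estimated correlation of 0.948, so these rates may not hold for the real libraries.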

Results

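Bulk RNA sequencing was performed on 24 libraries of mouse corpus callosum, the white matter tract that joins the cerebral hemispheres. Demyelination had been produced with cuprizone, a copper chelator that kills oligodendrocytes, the cells that make myelin. Some of the mice received a BTK inhibitor (BTKi), which the series summary places after disease was induced, and the others received vehicle. The labels also name naive mice that received BTKi. BTK (Bruton's tyrosine kinase) is a cytoplasmic kinase of B cells and myeloid cells, microglia included, that acts downstream of the B cell receptor and of Fc receptors. The groups were naive vehicle (n = 4), naive BTKi (n = 4), cuprizone vehicle (n = 8) and cuprizone BTKi (n = 8). The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be partly technical. The compound, its dose and the length of each treatment are not given in the sources used here.

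Expression was deposited as FPKM (fragments per kilobase of gene, scaled to the fragments of the library) for 54446 genes, of which 31917 were above 0 in at least 1 library. Between 14930 and 15435 genes reached 0.5 FPKM in each library. The spacing of the low values implied about 3.08e+07 fragments in the deepest library, 2.98e+07 in the second lowest and 2.65e+07 in the lowest, cuprizone BTKi 5. The first principal component carried 32.6% of the variance and separated naive libraries (-25.7 to -17.1) from cuprizone libraries (1.51 to 24.3). Changes are given as log2 differences of FPKM + 0.5, a scale that understates changes of low genes. Gene coordinates are those of GENCODE M21 on GRCm38. The build behind the FPKM values is not given in the sources used here.

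The comparison of cuprizone with naive mice under vehicle asked what the model itself changes in the tract. Myelin genes fell, and genes of activated microglia, interferon signalling and reactive astrocytes rose. Mbp, the basic protein that compacts myelin, fell from 1994 ± 355 FPKM (SD, n = 4) to 794 ± 116 FPKM (SD, n = 8), a log2 change of -1.33 (SE 0.15, limma adjusted p = 1.06e-06). Itgax, which encodes the integrin alpha X chain found on activated microglia, rose from 0.0747 ± 0.0276 to 5.29 ± 2.41 FPKM, a log2 change of 3.23 (SE 0.22, adjusted p = 1.01e-09). Gfap, the intermediate filament of astrocytes, rose from 64.5 ± 6.63 to 238 ± 54.4 FPKM (log2 change 1.85, SE 0.13, adjusted p = 1.01e-09). Mbp (ENSMUSG00000041607.16) is a protein-coding gene on the plus strand of chromosome 18, from 82475146 to 82585637. Itgax (ENSMUSG00000030789.9) is a protein-coding gene on the plus strand of chromosome 7, from 128129547 to 128150657.

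Among 15216 genes tested, 2288 passed an adjusted p of 0.05 in this comparison, 1555 higher and 733 lower. Of these, 173 were at least 2-fold higher and 68 at least 2-fold lower on the scale of the test. The direction of the smaller changes depended on the scaling: 1229 genes were higher and 978 lower after median ratio scaling, and 1205 higher and 1072 lower after quantile normalization. The largest rises among genes whose libraries did not overlap included Cst7, a cysteine protease inhibitor of activated microglia, which went from 0.135 ± 0.0476 to 15.2 ± 18.4 FPKM (log2 change 3.96, SE 0.56, adjusted p = 1.49e-05). Cst7 (ENSMUSG00000068129.5) lies on the plus strand of chromosome 2, from 150570415 to 150578944. Clec7a, a lectin receptor of myeloid cells, rose by a log2 change of 3.86 (SE 0.29, adjusted p = 2.88e-09). Cxcl10, an interferon-induced chemokine, rose from 0.403 ± 0.316 to 7.24 ± 2.69 FPKM (log2 change 3.09), and Ccl3, a chemokine of activated microglia, from 0.304 ± 0.0604 to 5.59 ± 3.57 FPKM (log2 change 2.76). Cd52, a surface glycoprotein of leukocytes, rose by a log2 change of 2.65, and Lyz2, the lysozyme of myeloid cells, by 2.58.

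Of 24 myelin and mature oligodendrocyte genes, 22 fell and none rose, with 23 lower when adjusted over the list alone. The mean score of the list, on the log2 scale, changed by -1.33 in cuprizone vehicle (95% interval -1.67 to -1.0, exact permutation p = 0.00202, the smallest possible, adjusted p = 0.00588). It also passed with an estimated correlation (camera adjusted p = 0.0344). Mal, a proteolipid of myelin, fell from 135 ± 15.6 to 27.6 ± 6.62 FPKM (log2 change -2.30, SE 0.20, adjusted p = 3.34e-08). Ppp1r14a, a phosphatase inhibitor abundant in oligodendrocytes, fell from 19.1 ± 2.69 to 3.79 ± 1.52 FPKM (log2 change -2.26). Fa2h, which hydroxylates the fatty acids of myelin lipids, changed by -2.03 and Mog, a surface protein of myelin, by -1.68. The naive vehicle 2 library had the highest myelin score, 1.25 against 0.74 to 0.81 in the other 3, and also the highest score of striatal neuron markers, 1.60 against 0.02 to 0.74. Those 8 striatal markers were all lower in cuprizone vehicle, by a mean score of -1.004.

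The earlier oligodendrocyte lineage did not move as a group. Pdgfra, the growth factor receptor that marks precursors, changed by 0.11 (SE 0.05, adjusted p = 0.111). Of 11 precursor genes, Emid1 rose by 0.32 and Cacng4 fell by 0.40, and the score changed by 0.02 (exact permutation, adjusted p = 0.695). Of 10 genes of newly formed oligodendrocytes, Rras2 rose by 0.24 and Fyn, a kinase of early myelination, by 0.12, while Enpp6, a marker of differentiating cells, fell by 0.57. The score of that list changed by 0.01 (adjusted p = 0.970). Counts adjusted over the list alone were 1 higher and 1 lower for the precursors, and 2 higher and 1 lower for newly formed cells. The calls of Emid1 (adjusted p = 0.0843 without naive vehicle 4), Fyn (0.141 without naive vehicle 3), Rras2 (0.201), Cacng4 (0.144) and Enpp6 (0.0547, these 3 without naive vehicle 2) each ended when 1 library was left out.

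Genes of the integrated stress response, which cells switch on when translation is blocked through eIF2 alpha, rose in 10 of 15 members, with 11 higher and 1 lower when adjusted over the list alone. The score was 0.82 higher (adjusted p = 0.00588, exact permutation test; camera adjusted p = 0.0550 with an estimated correlation). Nupr1, a stress-induced nuclear protein, rose from 6.28 ± 0.854 to 34.4 ± 6.45 FPKM (log2 change 2.35, adjusted p = 4.44e-08). The transcription factor Atf5 rose by 2.24, the secreted stress cytokine Gdf15 by 1.73 and the transcription factor Atf3 by 1.63.

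Of 23 genes of disease-associated microglia, the state microglia take on around damaged myelin and plaques, 21 rose, 22 when adjusted over the list alone. The score was 1.52 higher (95% interval 1.03 to 2.02, exact permutation p = 0.00202, adjusted p = 0.00588; camera adjusted p = 0.0907 with an estimated correlation). Besides Cst7, Clec7a and Itgax, the chemokine Ccl6 rose by 2.42. Trem2, the lipid receptor needed for this state, rose from 6.87 ± 0.583 to 24.9 ± 13.9 FPKM (log2 change 1.64, SE 0.27, adjusted p = 8.72e-05). Spp1, which encodes osteopontin, rose from 4.86 ± 1.43 to 30.9 ± 28.1 FPKM (log2 change 2.18, SE 0.44, adjusted p = 0.00103). The lysosomal protein Cd68 rose by 1.69, the lipid carrier Apoe by 0.98 and the microglial protein Aif1 by 0.93. Homeostatic microglia genes rose in 8 of 14, 10 when adjusted over the list alone, with a score 0.48 higher (adjusted p = 0.0259; 0.372 with an estimated correlation). Among them Fcrls rose by 1.21 and Csf1r, the receptor that microglia need to survive, by 0.93, while P2ry12, the purinergic receptor of resting microglia, changed by -0.02 (SE 0.07, adjusted p = 0.908). The call of the homeostatic list ended in 4 of the 24 fits without 1 library, with the highest adjusted p, 0.0727, without naive vehicle 2.

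All 16 measured genes of Fc receptor and BTK signalling rose (16 when adjusted over the list alone), and the score was 0.92 higher (adjusted p = 0.00588, exact permutation test; 0.0907 with an estimated correlation). Btk itself rose from 0.334 ± 0.0411 to 0.986 ± 0.385 FPKM (log2 change 0.80, SE 0.15, adjusted p = 0.000627). Btk (ENSMUSG00000031264.13) is a protein-coding gene on the minus strand of chromosome X, from 134542336 to 134583570. The inhibitory Fc receptor Fcgr2b rose by 1.49 and the activating receptor Fcgr3 by 1.48. Complement genes rose in 9 of 10 (10 when adjusted over the list alone), with a score 1.08 higher (adjusted p = 0.00588; 0.0435 with an estimated correlation). C4b rose from 5.72 ± 0.714 to 22.0 ± 4.24 FPKM (log2 change 1.84) and C1qa, part of the first complement component, by 1.58.

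All 19 interferon response genes rose (19 when adjusted over the list alone), with a score 1.59 higher (95% interval 1.22 to 1.96, exact permutation p = 0.00202, adjusted p = 0.00588; 0.0435 with an estimated correlation). Oasl2, an antiviral oligoadenylate synthetase-like protein, rose from 2.21 ± 0.108 to 12.7 ± 3.96 FPKM (log2 change 2.23), Ifit3 by 1.93 and Ifit1 by 1.72. All 9 genes of MHC class I presentation rose (9 when adjusted over the list alone; score 0.96 higher, adjusted p = 0.00588; 0.0762 with an estimated correlation), among them H2-D1 by 1.35 and B2m, the light chain of class I molecules, by 1.15. Of 6 genes of MHC class II presentation, 5 rose (6 when adjusted over the list alone; score 0.92 higher, adjusted p = 0.0149; 0.180 with an estimated correlation), and the invariant chain Cd74 rose by 1.84. Of 8 cytokines and chemokines, 7 rose (7 when adjusted over the list alone; score 1.48 higher, adjusted p = 0.00588; 0.0435 with an estimated correlation), among them Ccl4 by 2.39 and Ccl5 by 1.88. Of 12 genes of phagocytosis and the lysosome, 8 rose (8 higher and 1 lower when adjusted over the list alone; score 0.62 higher, adjusted p = 0.0149; 0.303 with an estimated correlation), among them the protease Ctss by 1.71 and the integrin Itgb2 by 1.43. The call of this last list ended without naive vehicle 4 (adjusted p = 0.0554).

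Genes of cholesterol biosynthesis, a pathway that oligodendrocytes use heavily to make myelin, fell in 17 of 19 (18 when adjusted over the list alone). The score changed by -0.33 (adjusted p = 0.00588, exact permutation test; 0.00146 with an estimated correlation). Msmo1, a sterol oxidase, fell from 44.7 ± 1.03 to 30.0 ± 2.14 FPKM (log2 change -0.57, adjusted p = 3.09e-07), and the isomerase Idi1 changed by -0.53 and the synthase Hmgcs1 by -0.43. Among 13 genes of cholesterol efflux and LXR targets, 6 rose and 1 fell, the same when adjusted over the list alone. The exporter Abca1 rose by 0.91 and the lipid droplet protein Plin2 by 0.63, while Npc1, which moves cholesterol out of lysosomes and was named after its value was seen, fell by 0.36. The score of that list was 0.28 higher (adjusted p = 0.0283; 0.664 with an estimated correlation), and its call ended in 3 of the 24 fits without 1 library (highest adjusted p = 0.0727, without naive vehicle 1).

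Reactive astrocyte genes rose in 10 of 11 (10 when adjusted over the list alone; score 1.28 higher, adjusted p = 0.00588, exact permutation test; 0.0435 with an estimated correlation). Besides Gfap, the protease inhibitor Serpina3n rose from 8.65 ± 1.00 to 35.9 ± 11.6 FPKM (log2 change 1.94), the cytokine receptor Osmr by 1.76 and Lcn2, an iron-binding secreted protein, from 0.165 ± 0.124 to 5.41 ± 6.24 FPKM (log2 change 2.42, SE 0.69, adjusted p = 0.0160). General astrocyte genes moved both ways, 4 higher and 1 lower of 12 (the same when adjusted over the list alone): the glutamate transporter Slc1a3 rose by 0.51 and the gap junction protein Gja1 fell by 0.23. The score of that list was 0.14 higher (adjusted p = 0.0259; 0.455 with an estimated correlation; 0.0606 after median ratio scaling), and the call of Gja1 ended without naive vehicle 2 (adjusted p = 0.0878).

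Striatal neuron markers, from outside the tract, differed between the same groups. All 8 striatal neuron markers fell (8 when adjusted over the list alone; score change -1.004, 95% interval -1.57 to -0.44, exact permutation p = 0.00202, adjusted p = 0.00588; 0.134 with an estimated correlation). The dopamine receptor Drd2 fell from 12.8 ± 8.22 to 4.56 ± 1.52 FPKM (log2 change -1.28, SE 0.35, adjusted p = 0.0142), the adenosine receptor Adora2a changed by -1.22 and the signalling regulator Rgs9 by -0.98. Without naive vehicle 2 none of these 3 calls held (adjusted p = 0.107, 0.0546 and 0.0861). The 14 general neuron genes gave 0 calls by limma (1 higher and 3 lower at an unadjusted p under 0.05), and their score changed by 0.01 (exact permutation, adjusted p = 0.823).

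**Figure D1:**
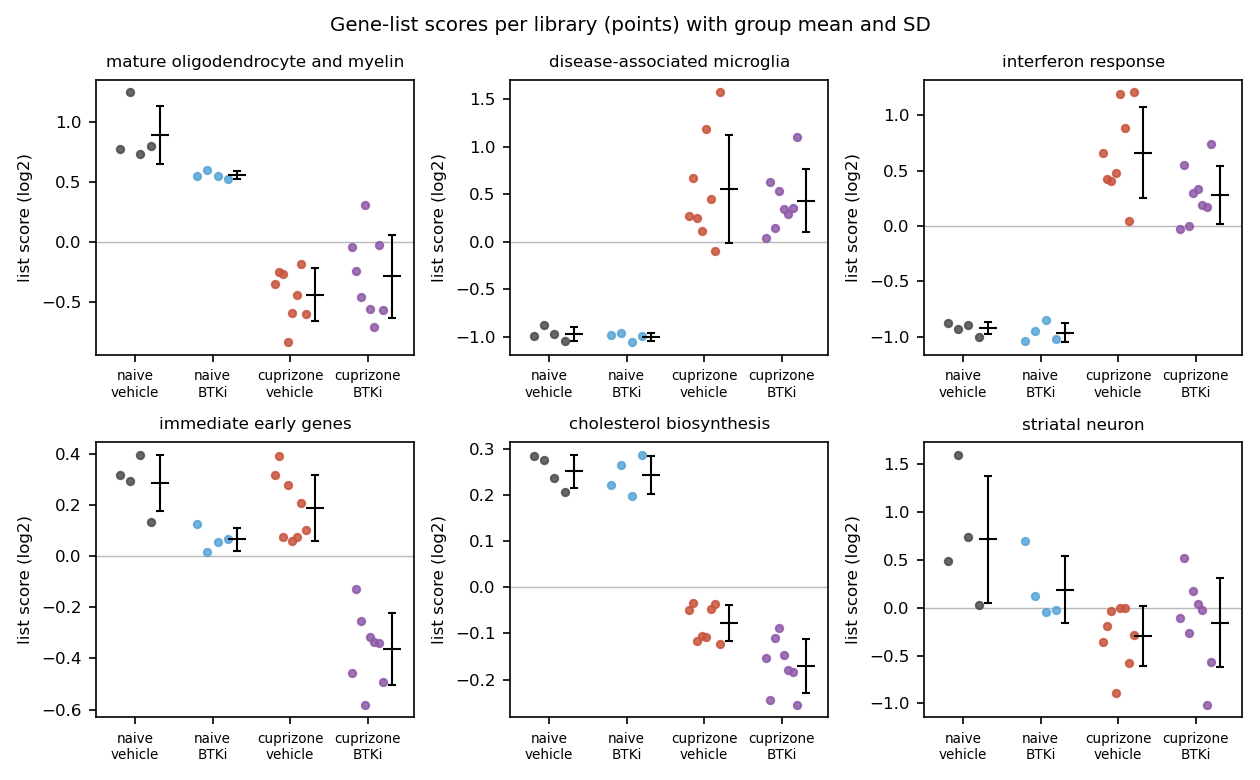
Scores of 6 gene lists (vertical axis, mean gene-centred log2 of FPKM + 0.5 over the measured members) in each of the 24 libraries, by group, with 1 point per library and the group mean ± SD. Myelin scores were lower and microglial and interferon scores higher in both cuprizone groups than in the naive groups, and immediate early gene scores were lower in cuprizone BTKi (-0.36 ± 0.14) than in cuprizone vehicle (0.19 ± 0.13).

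The comparison of BTKi with vehicle in cuprizone mice asked what the inhibitor changes in demyelinated tissue. Immediate early genes, which cells transcribe within minutes of a stimulus, were lower under BTKi, and the myelin, microglial and astrocyte genes that cuprizone had moved were not called. Nr4a1, an orphan nuclear receptor induced by stimulation, fell from 63.7 ± 6.93 to 32.6 ± 4.20 FPKM (SD, n = 8 each), a log2 change of -0.96 (SE 0.07, limma adjusted p = 2.4e-08). Arc, a regulator of synapses that is transcribed on neuronal activity, fell from 129 ± 21.2 to 65.3 ± 13.6 FPKM (log2 change -0.98, SE 0.10, adjusted p = 4.9e-06). Junb, a subunit of the AP-1 transcription factor, fell from 51.2 ± 7.61 to 28.0 ± 3.09 FPKM (log2 change -0.86, SE 0.08, adjusted p = 6.14e-07). All 3 are protein-coding. Nr4a1 (ENSMUSG00000023034.7) lies on the plus strand of chromosome 15, from 101254269 to 101274795, and Arc (ENSMUSG00000022602.14) on the minus strand of the same chromosome, from 74669083 to 74672570. Junb (ENSMUSG00000052837.6) lies on the minus strand of chromosome 8, from 84974484 to 84978718.

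In all, 27 of 15216 genes passed, 6 higher and 21 lower, none of them by 2-fold, and 1338 had an unadjusted p under 0.05. The split was 6 higher and 15 lower after median ratio scaling, and 8 higher and 13 lower after quantile normalization. The count fell by more than 1.5 times without cuprizone vehicle 2 (14 genes) or 4 (17), and without cuprizone BTKi 1 (17), 3, 7 or 8 (16 each). It was 16 without the filter on low values. It was 11 without the 3 cuprizone vehicle libraries poor in choroid plexus RNA, an alternative chosen after the data were seen. The score of choroid plexus genes was -1.90, -2.36 and -2.28 in those libraries, and the list's score differed by 0.65 between the groups (exact permutation, adjusted p = 0.926). Without them Dusp1 was no longer called (adjusted p = 0.0707).

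Of the 12 immediate early genes, 8 fell and none rose, with 10 lower when adjusted over the list alone. The score changed by -0.55 under BTKi (95% interval -0.68 to -0.42, exact permutation p = 0.000155, adjusted p = 0.00497), and it passed with an estimated correlation too (camera adjusted p = 0.000358). Ier2 fell from 9.13 ± 1.57 to 5.15 ± 0.502 FPKM (log2 change -0.76, adjusted p = 4.9e-06). Dusp1, a phosphatase that switches off MAP kinases, changed by -0.59 (adjusted p = 0.00161), and Fos, a partner of Jun proteins in AP-1, by -0.54 (adjusted p = 0.00171). Btg2, an antiproliferative gene named here after its value was seen, fell from 6.80 ± 0.782 to 4.91 ± 0.489 FPKM (log2 change -0.43, adjusted p = 0.00154). Npas4, a transcription factor of active neurons also named after its value was seen, did not pass (log2 change -0.58, limma adjusted p = 0.0852). The score of the 14 general neuron genes, which share the tissue pieces with these genes, differed by -0.03 (adjusted p = 0.926).

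Nostrin, which regulates nitric oxide synthase trafficking in endothelium, rose from 2.17 ± 0.237 to 3.27 ± 0.388 FPKM (log2 change 0.50, SE 0.07, adjusted p = 0.000193). Nostrin (ENSMUSG00000034738.8) is protein-coding and lies on the plus strand of chromosome 2, from 69135800 to 69189330. Zbtb16, a zinc finger transcription factor induced by glucocorticoids, rose from 7.75 ± 0.680 to 10.5 ± 0.875 FPKM (log2 change 0.41, SE 0.06, adjusted p = 0.00096). In naive mice the BTKi changes, given after they were seen, were 0.40 for Nostrin (limma adjusted p = 0.0654) and 0.31 for Zbtb16 (0.137). The difference of the BTKi effects was called for neither gene (limma adjusted p = 0.806 and 0.768). Both genes were also higher after cuprizone under vehicle (0.54 and 0.23). Map3k6, a stress-activated kinase, rose by 0.43 (adjusted p = 0.0411), a call that ended in 15 of the 24 fits without 1 library (highest adjusted p = 0.101, without cuprizone vehicle 2). Per1, a clock gene named after its value was seen, fell by 0.27 (adjusted p = 0.0474), and its call also ended in 15 of those fits (highest adjusted p = 0.103, without cuprizone BTKi 7).

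Btk went from 0.986 ± 0.385 to 0.787 ± 0.238 FPKM under the inhibitor, a log2 change of -0.19 that did not pass (SE 0.13, adjusted p = 0.705). None of 16 genes of Fc receptor and BTK signalling passed by limma (0 at an unadjusted p under 0.05), none of 24 myelin genes (0 at that p) and none of 23 genes of disease-associated microglia (1 lower at that p). Mbp was at 968 ± 267 FPKM against 794 ± 116 (log2 change 0.26, SE 0.12, adjusted p = 0.574), Mog at a change of 0.24 (0.781) and Mal at 0.33 (0.601). The myelin score differed by 0.15 (95% interval -0.12 to 0.42, exact permutation p = 0.315) and that of disease-associated microglia by -0.12 (95% interval -0.53 to 0.29, exact permutation p = 0.618), each with an adjusted p of 0.933. Trem2 changed by -0.12, Itgax by -0.28, Cd68 by -0.14, Spp1 by -0.39, Csf1, the ligand of Csf1r, by -0.28, Apoe by 0.05, Aif1 by 0.16, P2ry12 by 0.10, Csf1r by -0.01, Fcgr2b by 0.00, Pdgfra by -0.05 and Gfap by -0.01, and none of these passed (adjusted p from 0.279 to 0.997).

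The interferon response list had 0 of 19 genes called over all genes tested (limma; 13 lower at an unadjusted p under 0.05), and 12 lower when adjusted over the list alone. Its score changed by -0.38 (95% interval -0.68 to -0.08, exact permutation p = 0.0457), which did not pass over the 32 lists (adjusted p = 0.487; 0.522 with an estimated correlation). Ifit1 went from 4.64 ± 1.36 to 2.82 ± 0.576 FPKM (log2 change -0.61, SE 0.13, adjusted p = 0.0586) and Ifit3 from 25.9 ± 6.41 to 18.1 ± 3.55 FPKM (log2 change -0.49, adjusted p = 0.118). The score of cholesterol biosynthesis changed by -0.09 (exact permutation p = 0.00249, adjusted p = 0.0398; 0.162 with an estimated correlation), with 0 of 19 genes called by limma (11 lower at an unadjusted p under 0.05) and 7 lower when adjusted over the list alone. Its members Fdps (log2 change -0.15, adjusted p = 0.182) and Insig1 (-0.16, adjusted p = 0.314) had the smallest p. The call of this list ended in 12 of the 24 fits without 1 library (highest adjusted p = 0.0970, without cuprizone vehicle 1), after median ratio scaling (0.139) and with the median over members (0.0845).

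**Figure D2:**
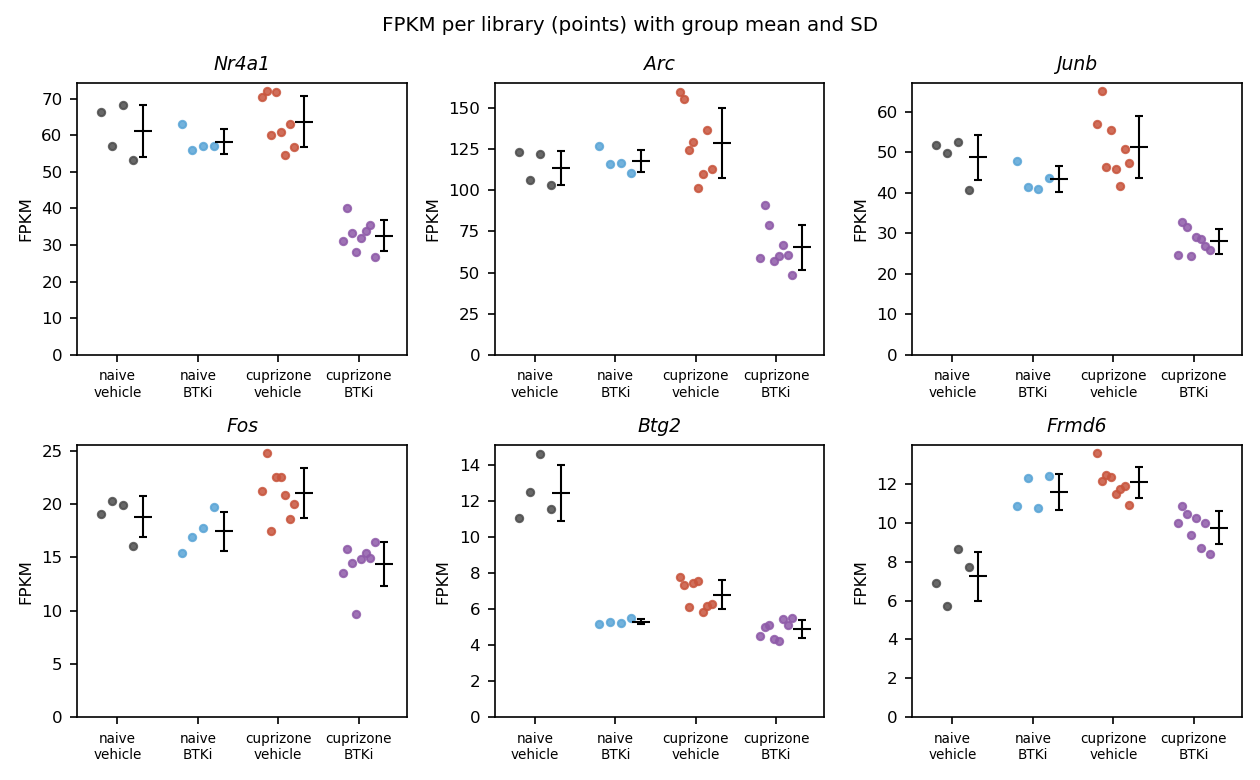
FPKM (vertical axis, starting at 0) of Nr4a1, Arc, Junb, Fos, Btg2 and Frmd6 in each library of the 4 groups, with 1 point per library and the group mean ± SD. Nr4a1 lies between 26.8 and 40.2 in the 8 cuprizone BTKi libraries and between 54.5 and 72.2 in the 8 cuprizone vehicle libraries, while Btg2 lies between 11.1 and 14.6 in naive vehicle and at most at 7.76 in the other 3 groups.

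The comparison of BTKi with vehicle in naive mice asked what the inhibitor changes without demyelination. Of the genes called, 16 rose and 17 fell. Btg2 fell from 12.4 ± 1.55 to 5.30 ± 0.137 FPKM (SD, n = 4 each), a log2 change of -1.15 (SE 0.09, limma adjusted p = 1.09e-07). Frmd6, a scaffold of the Hippo pathway, rose from 7.25 ± 1.25 to 11.6 ± 0.906 FPKM (log2 change 0.65, SE 0.09, adjusted p = 0.00158), and the clock gene Per2 from 6.21 ± 0.350 to 9.48 ± 0.324 FPKM (log2 change 0.57, SE 0.09, adjusted p = 0.00317). Btg2 (ENSMUSG00000020423.6) is a protein-coding gene on the minus strand of chromosome 1, from 134075170 to 134079120, and Frmd6 (ENSMUSG00000048285.9) one on the plus strand of chromosome 12, from 70825514 to 70902234.

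Of 15216 genes, 33 passed, 16 higher and 17 lower, with 1 at least 2-fold lower, and 1922 had an unadjusted p under 0.05. The split was 23 higher and 16 lower after median ratio scaling, and 22 higher and 7 lower after quantile normalization. The smooth muscle protein Tagln rose by 0.55, the transcription factor Klf10 by 0.51, the neural transcription factor Sox21 by 0.49 and the immediate early response gene Ier5 by 0.49. Per1 (log2 change 0.40, adjusted p = 0.0332) and Stk40 (from 10.5 ± 0.366 to 13.5 ± 0.217 FPKM, log2 change 0.35, adjusted p = 0.00324) were named after their values were seen. The cilium protein Cfap44 fell by 0.78, the linker histone Hist1h1e by 0.63, the Wnt inhibitor Notum by 0.56, the arrestin family member Arrdc3 by 0.55 and Ankrd34c by 0.52. Of these 14 genes, Btg2, Frmd6, Per2 and Stk40 were called in each of the 24 fits without 1 library. The other 10 were each lost in at least 1 fit, 10 of the 14 without naive BTKi 3 (adjusted p from 0.0633 to 0.203), 10 without naive BTKi 4 (0.0648 to 0.149) and 10 without naive vehicle 2 (0.0509 to 0.143). The other 5 naive libraries each ended 5 to 8 of these calls. The count was 11 without naive vehicle 2, 21 without naive BTKi 1, 8 without naive BTKi 3 and 7 without naive BTKi 4. It was 21 without the filter, 3 with only the naive libraries in the fit, 145 with array weights, and 8 with the striatal score as a covariate and 19 without the choroid-poor libraries, the last 2 chosen after the data were seen.

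No gene list passed in naive mice by the exact permutation test (4 had an unadjusted p under 0.05), by fry or by camera with an estimated correlation, while 3 passed camera with its preset correlation. With 4 against 4 libraries the exact permutation p cannot go below 0.0286. Immediate early genes reached that value with a score difference of -0.22, the myelin list with -0.34 (95% interval -0.72 to 0.05), newly formed oligodendrocytes with -0.15 and B cell genes with -0.45, and each had an adjusted p of 0.229. Of the 12 immediate early genes only Btg2 was called, with 3 lower when adjusted over the list alone. Npas4, named after its value was seen, changed by -0.85 (limma adjusted p = 0.0634). Mbp went from 1994 ± 355 to 1655 ± 37.0 FPKM (log2 change -0.25, SE 0.18, adjusted p = 0.576) and Mog changed by -0.34, and neither passed. The striatal score changed by -0.52 (exact permutation p = 0.229), beside the myelin values. Btk changed by 0.02 (SE 0.18, adjusted p = 0.980).

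Of the 33 genes, 27 were also called for cuprizone under vehicle, all in the same direction, a comparison that uses the same naive vehicle libraries. The higher genes shared 16 calls against 1.64 from independent lists, and the lower genes 11 against 0.819. The sign was the same for 97.0% of the 33 genes, and 21 of 69 other labellings of the naive libraries, which keep the shared controls, gave a share as high (median 90.9%, highest 100%). With the naive vehicle libraries split between the comparisons in 6 ways the median share was 97.0%, for genes that had been chosen with all 4. In the cuprizone comparison under BTKi, 4 of the 33 were called, and it shares the naive BTKi libraries, with the opposite sign, so it is no independent check.

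The difference between the BTKi effects in cuprizone and in naive mice was tested for each gene, since a call in one and not in the other does not show a difference. Frmd6, Nr4a1, Per1, Stk40 and Btg2 had the smallest p. The BTKi effect on Frmd6 in cuprizone minus that in naive mice was -0.95 (SE 0.11, limma adjusted p = 0.000155), and that on Nr4a1 was -0.90 (SE 0.13, adjusted p = 0.00187). The difference was -0.67 for Per1 (adjusted p = 0.00187), -0.44 for Stk40 (0.00254) and 0.72 for Btg2 (SE 0.12, adjusted p = 0.00543). In cuprizone mice the BTKi change was not called for Frmd6 (-0.30, limma adjusted p = 0.0586) or Stk40 (-0.096, 0.454). Stk40 had a mean of 10.5 FPKM in naive vehicle against 13.5 in naive BTKi, 15.3 in cuprizone vehicle and 14.3 in cuprizone BTKi. Btg2 had 12.4 against 5.30, 6.80 and 4.91 in the same order. For Stk40 and Btg2 the difference thus rests largely on the naive vehicle libraries, and a difference of those libraries other than the drug is not excluded. Per1 (ENSMUSG00000020893.17) is a protein-coding gene on the plus strand of chromosome 11, from 69095217 to 69109960. Arc (-1.03, adjusted p = 0.0103), Klf10 (-0.81, 0.00548) and Junb (-0.70, 0.0305) were named after their values were seen.

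In all, 19 of 15216 genes passed, 1 with a higher and 18 with a lower effect in cuprizone, and 1482 had an unadjusted p under 0.05. The count was 11 without naive vehicle 2, 12 without naive vehicle 4, 11 without naive BTKi 3, 8 without naive BTKi 4, 9 with the replicate number as a block, where the calls of Btg2 (adjusted p = 0.0543) and Junb (0.0555) ended, 11 with the striatal score as a covariate and 7 without the choroid-poor libraries. Junb was also lost in 11 of the 24 fits without 1 library (highest adjusted p = 0.101, without naive BTKi 1). Of the 12 immediate early genes, 3 passed with a lower effect in cuprizone and 1, Btg2, with a higher one, 7 lower and 1 higher when adjusted over the list alone. The score difference was -0.33 (permutation p = 0.0744). No list passed by permutation (2 of 32 had an unadjusted p under 0.05, smallest adjusted p = 0.426) or by fry, and 8 passed camera with its preset correlation. The difference was 0.49 for the myelin score (permutation p = 0.0198) and 0.66 for the striatal score (p = 0.139).

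The comparison of cuprizone with naive mice under BTKi asked whether the model changes the tract in the same way when the inhibitor is given. Mbp fell from 1655 ± 37.0 to 968 ± 267 FPKM (SD, n = 4 and 8; log2 change -0.82, SE 0.15, limma adjusted p = 0.000747) and Mog changed by -1.09 (adjusted p = 0.00393). Itgax rose by 2.94 (SE 0.22, adjusted p = 5.21e-09), Gfap by 1.93, Trem2 by 1.58, Apoe by 0.92, Cxcl10 by 2.47 and Btk by 0.59 (adjusted p = 0.0145). The score of the myelin list changed by -0.84 (95% interval -1.18 to -0.51, exact permutation p = 0.00404), that of the interferon response 1.25 higher (0.88 to 1.62) and that of disease-associated microglia 1.43 higher (0.93 to 1.93), the last 2 with an exact permutation p of 0.00202. These scores were chosen for this comparison after the data were seen. The immediate early gene score changed by -0.43 (exact permutation p = 0.00202), and the striatal score differed by -0.34 (95% interval -0.91 to 0.22, exact permutation p = 0.226).

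Of 15216 genes, 1198 passed, 929 higher and 269 lower, with 142 and 22 of them changed at least 2-fold. The split was 772 higher and 406 lower after median ratio scaling, and 724 higher and 395 lower after quantile normalization. Of these genes 879 were also called under vehicle, 669 higher in both against 94.9 from independent lists and 205 lower in both against 13.0, and the pair of comparisons shares no libraries. Another 1409 genes were called only under vehicle and 319 only under BTKi, and 2045 of the 2288 genes called under vehicle had the same sign under BTKi. The difference of the 2 cuprizone changes is, gene by gene, the same quantity as the difference of the BTKi effects. It was called for 19 genes. A call in only 1 of these comparisons therefore does not show that BTKi altered the cuprizone change. With the striatal score as a covariate, chosen after the data were seen, 1244 genes were called under vehicle and 1265 under BTKi.

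**Figure D3:**
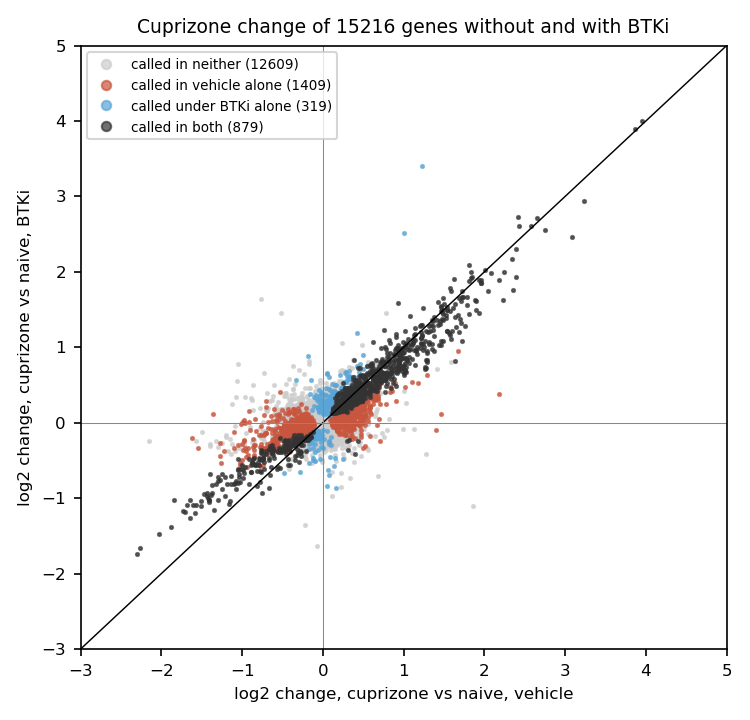
Log2 change of FPKM + 0.5 after cuprizone under vehicle (horizontal axis) and under BTKi (vertical axis), with 1 point for each of 15216 genes, coloured by the comparison that called it, and a diagonal line of equal change. Of the 879 genes called in both comparisons, 874 lie on the same side of 0 on both axes.

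Whether BTKi moved the cuprizone genes back toward the naive level was examined over the 2288 genes called under vehicle. The BTKi change was computed against a different 4 of the cuprizone vehicle libraries than the cuprizone change, since shared libraries alone give a negative correlation. The median Pearson correlation across genes over 70 splits was -0.463 (range -0.731 to 0.168), with a median slope of -0.0957. A median of 68.7% of genes had opposite signs, a share not computed for permuted labels. The genes were chosen with all cuprizone vehicle libraries, so the splits do not remove the effect of that choice, which the permuted draws share. With the drug labels permuted among the cuprizone libraries the median correlation was -0.172. Of 100 draws 22 were as low (one-sided permutation p = 0.228), so the return was not larger than the spread between libraries gives. Without splitting the correlation was -0.550 against -0.277 in permuted draws, and the covariance was -0.0402 against -0.0155 (split, -0.0368 against -0.0108). Genes are not independent replicates.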

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

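The tests of neuronal RNA, striatal tissue, shared controls and other splits of the libraries were chosen only after the result was seen, and those of time of day after the genes that prompted them but before their own values. Immediate early genes fell under BTKi in cuprizone mice, with 8 of 12 called. Less neuronal RNA in those libraries is argued against. With neuron, hippocampal and striatal scores as covariates, limma still called 7 of the 12 genes. Their median change was -0.54 with the covariates and -0.57 without. The SE of that median, 0.11, measures the spread between the 12 genes, which are correlated, and not between libraries. A different time of day at collection may contribute and cannot be told apart, since a contrast of 10 clock genes differed by -0.108 (95% interval -0.22 to 0.01, exact permutation p = 0.0791). A drug effect stays open and untested, as does any other difference between the groups in how the samples were taken. The immediate early gene list had been set beforehand as one of tissue quality. Of 100 splits of the cuprizone libraries 2, the real one included, gave as many as 27 genes and the highest other gave 36. That argues against chance at 5 in 100. It does not exclude chance, since few of the possible splits were drawn and 1 other split exceeded the real count.

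Striatal markers fell after cuprizone under vehicle, where 2288 genes were called against 1198 under BTKi. Different amounts of striatal tissue in the dissected pieces are a candidate explanation, since the 28 pairs of markers correlated within groups by a median r of 0.952 (0.894 to 0.981; 0.940 without naive vehicle 2). With the striatal score as a covariate the ratio of the counts was 0.983 (1.91 without it) and 796 genes were called in both. The striatal score differed by -1.004 between cuprizone and naive mice under vehicle and by -0.344 under BTKi. The covariate therefore takes more from the comparison under vehicle whatever the cause, so the ratio cannot decide between explanations. A cuprizone effect on striatal neurons cannot be told apart, because the change under BTKi minus that under vehicle was 0.66 (95% interval -0.14 to 1.46). Myelin genes were still lower with the covariate (21 of 24 called, 22 without it; median log2 change -1.18 against -1.34), and 1 of 100 splits, the real one, gave as many genes under vehicle (highest other 689) and 1 of 100 under BTKi (highest other 79), which excludes chance for both counts.

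The 33 genes called for BTKi in naive mice moved alike with cuprizone. The sign was the same for 97.0% of the genes, and 21 of 69 other labellings of the naive libraries, which keep the shared naive vehicle libraries, gave a share as high. Chance values of those shared libraries cannot be told apart as an explanation: with 33 genes chosen using 2 of them and the cuprizone change taken against the other 2, the median share was 84.8%, which 0 of 69 other labellings reached (highest 78.8%), but the lowest of the 6 ways to choose them, 72.7%, missed the bound of 75% set for excluding it. A different time of day at collection of the naive vehicle libraries cannot be told apart, since the clock contrast differed by 0.0493 (95% interval -0.12 to 0.21, exact permutation p = 0.543) here and by 0.164 for cuprizone under vehicle (p = 0.0222), and a drug effect stays open. Of 35 splits of the naive libraries 1, the real one, gave as many as 33 genes (highest other 0), which excludes a chance split of these libraries but not a difference between them other than the drug.

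For the difference of the BTKi effects 2 of 100 splits gave as many as 19 genes, the real one included, and the highest other gave 64. A split with several times the real count may reflect a structure of the samples other than the groups, which was not tested. Differences of the BTKi effect between cuprizone and naive mice were called for Btg2 (0.72), Arc (-1.035), Nr4a1 (-0.90), Junb (-0.70), Frmd6 (-0.95), Klf10 (-0.81), Per1 (-0.67) and Stk40 (-0.44).

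Single libraries lay far from the rest of their group in 31 of 528 groups tested, where chance gives about 1 in 20 (26.4). In naive vehicle 2 these were the FPKM of Ppp1r14a (23.1, others 17.4 to 17.9) and Enpp6 (5.54) and the scores of myelin (1.25), newly formed oligodendrocytes (0.28) and general neurons (-0.14). In the other naive vehicle libraries they were Idi1 in 1 (20.1 FPKM), Tagln in 3 (3.79) and Btk in 4 (0.272, others 0.351 to 0.356). In naive BTKi 1 they were Gja1 (44.5 FPKM), Adora2a (9.35), Nr4a1 (63.2), Stk40 (13.2), the scores of precursors (-0.0253), the integrated stress response (-0.56) and hippocampal neurons (0.13), and the total FPKM (496350). In naive BTKi 2 the complement score was -0.67, and in naive BTKi 3 Ccl4 was at 0.1003 FPKM while the other 3 libraries were listed at 0.

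In cuprizone BTKi 8 the FPKM of Fcgr2b (10.3), Spp1 (58.0, others 10.6 to 22.3), Fcrls (33.4) and Fn1 (18.1) and the general astrocyte score (0.20) lay apart. In cuprizone BTKi 4 these were Fos (9.72 FPKM) and Arrdc3 (10.5), in cuprizone BTKi 2 Map3k6 (5.21), in cuprizone BTKi 3 the percent of FPKM in haemoglobin genes (0.0873%), and in cuprizone BTKi 5 the depth (85.9% of the deepest library). In cuprizone vehicle 2 Fibcd1 was at 10.6 FPKM (others 7.07 to 8.45), and in cuprizone vehicle 8 the B cell score was 1.44 and the monocyte and border macrophage score 0.32.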

How the results depend on the processing

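The striatal covariate and the choroid-poor alternative were added only after the data were seen; all others were chosen before. Counts of genes not listed here stayed within 1.5 times. For BTKi in cuprizone, 27 genes became 16 without the filter, 11 without the choroid-poor libraries and 0 with a 2-fold minimum as well (limma; 1338 at an unadjusted p under 0.05). For BTKi in naive mice, 33 genes became 21 without the filter, 3 with only the 2 groups in the fit, 145 with array weights, 8 with the striatal covariate, 19 without the choroid-poor libraries and 1 with the 2-fold minimum. For the difference of the BTKi effects, 19 genes became 9 with the replicate block, 11 with the striatal covariate, 7 without the choroid-poor libraries and 1 with the 2-fold minimum. The 2-fold minimum left 241 genes for cuprizone under vehicle and 164 under BTKi, and the striatal covariate left 1244 under vehicle. Drd2 (0.15), Rgs9 (0.0727) and Cd4 (0.0201) reversed with that covariate, in cuprizone under vehicle. Drd2 and Rgs9 are members of that score, so the loss of their change follows from its construction, as do fewer genes from the 2-fold minimum, and the cause of the other moves was not tested.

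Leaving out each library gave 1825 to 2392 genes for cuprizone under vehicle, 14 to 34 for BTKi in cuprizone, 7 to 41 for BTKi in naive mice, 8 to 23 for the difference and 860 to 1294 for cuprizone under BTKi. List calls ran from 13 to 17, 1 to 2, 0 to 0 and 0 to 0 for the first 4 (exact permutation tests; 4 and 2 lists at an unadjusted p under 0.05 for the last 2), and the correlation of return from -0.593 to -0.357 over 12 libraries. For BTKi in naive mice the lack of list calls follows largely from the lowest p that so few libraries allow, so it does not show stability. With all tested genes the correlation of return was -0.179. Camera with its preset correlation passed 8 lists for BTKi in cuprizone, 3 in naive mice and 8 for the difference, with an estimated correlation 6 for cuprizone under vehicle and 1 for BTKi in cuprizone, and with the replicate block 12, 2 and 7 for BTKi in cuprizone, in naive mice and the difference. Median ratio scaling and the median over members each left 1 list for BTKi in cuprizone. For cuprizone under vehicle they ended the call of general astrocytes (adjusted p = 0.0606 and 0.0646), and fry that of cholesterol efflux (0.0512).

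The labels do not state that the replicate numbers pair the libraries, and a partial pairing is not excluded. Over 28 pairs with the same number, deviations from the group means correlated by -0.274 to 0.324. The median was 0.00148, against -0.00338 for different numbers, and 8 pairs exceeded 0.1. Of the 24 libraries, 9 correlated best with their own number, and the number that chance gives was not computed. Few of the libraries compared with each one carry its number, so the medians near 0 do not show that pairing is absent. With the replicate block 1859, 26, 27 and 1009 genes were called for cuprizone under vehicle, BTKi in cuprizone, BTKi in naive mice and cuprizone under BTKi. Without it the counts were 2288, 27, 33 and 1198. For the difference of the BTKi effects, 9 genes were called with the block and 19 without it. For single genes, alternatives chosen before left 9683 values with the same direction and side of the threshold. Another 263 were no longer past it and 17 were newly past it. A further 60 values, past the threshold in neither fit, changed direction. The added alternatives gave 513, 45, 0 and 15, with 3 that changed direction and were past the threshold in 1 fit. Depth limits low genes, where 1 fragment is a large step.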

Other observations

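Of the tests in this part, the striatal score as a covariate was chosen only after the result was seen, and the glucocorticoid test was set after the genes that prompted it but before its value. After cuprizone under vehicle none of the remaining lists, of other cell types and of tissue quality, passed over the 32 lists. Of 3 B cell genes Cd22, an inhibitory receptor of B cells that microglia also make, rose from 0.134 ± 0.0690 to 1.31 ± 0.560 FPKM (SD, n = 4 and 8; log2 change 1.46, SE 0.18, limma adjusted p = 3.1e-06), and the score changed by 0.28 (exact permutation, adjusted p = 0.443). Of 4 T and NK cell genes Cd4 fell by 1.05 (adjusted p = 0.00885; score -0.18, adjusted p = 0.155), a call that ended without naive vehicle 2 (adjusted p = 0.0761) and that reversed to 0.02 with the striatal score as a covariate. Of 3 monocyte and border macrophage genes the mannose receptor Mrc1 rose by 0.31 (score 0.25, adjusted p = 0.101), of 8 mural genes Tagln by 0.52 (score 0.11, adjusted p = 0.119) and of 8 fibroblast and meninges genes Fn1, which encodes fibronectin, by 0.51 (score 0.03, adjusted p = 0.853). Of 6 hippocampal genes Fibcd1 rose by 0.30 (score 0.10, adjusted p = 0.443) and of 10 choroid plexus genes the prolactin receptor Prlr fell by 1.27 (score -1.31, adjusted p = 0.101). Without naive vehicle 2 the calls of Mrc1 (adjusted p = 0.223), Fn1 (0.145) and Prlr (0.121) ended, and without naive vehicle 4 that of Fibcd1 (0.211). Counts adjusted over the list alone were 1 higher for the B cell, monocyte, mural and hippocampal lists, 1 lower for T and NK cells, 1 higher and 1 lower for fibroblasts and 10 lower for choroid plexus.

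Of 12 immediate early genes Btg2 (-0.82) and Npas4 (-0.74) fell after cuprizone under vehicle, with a score change of -0.10 (exact permutation, adjusted p = 0.295). By limma 0 genes were called in 4 further lists, the 8 proliferation genes (2 higher at an unadjusted p under 0.05; score 0.14, adjusted p = 0.302), the 6 ependyma genes (2 lower; -0.39, 0.212), the 10 endothelium genes (0; 0.01, 0.859) and the 9 mitochondrially encoded genes (0; -0.11, 0.328). The 4 red blood cell genes also gave 0 calls (0 at an unadjusted p under 0.05; score 0.66, adjusted p = 0.273). Only 1 sex-linked gene was measured (score 0.06, exact permutation p = 0.396) and no neutrophil gene, so neither list was tested among the 32.

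Zbtb16 and Map3k6, which glucocorticoids can raise, were higher under BTKi in cuprizone mice, and a glucocorticoid response was tested as a hypothesis. Over 10 other measured glucocorticoid targets the score was 0.0866 higher under BTKi (95% interval 0.01 to 0.16, exact permutation p = 0.0359, 8 against 8 libraries). A p under 0.05 had been set as what the hypothesis predicts, and an interval below 0.2 as what would exclude it, and the value met both, since the limits had not been made exclusive. Read by the limit, a response of 0.2 or more is argued against, and a smaller one stays open. By limma none of the 10 targets was called under BTKi in cuprizone (smallest adjusted p = 0.234, Bcl6). The score was also 0.147 higher after cuprizone under vehicle (exact permutation p = 0.00202) and differed by 0.0969 under BTKi in naive mice (p = 0.114). The rise after cuprizone leaned on Cdkn1a, with a log2 change of 1.17. Tsc22d3 (-0.22), Sgk1 (-0.14), Pdk4 (-0.14) and Ddit4 (-0.22) were lower there, and the others changed by 0.05 to 0.34.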
